A study of Drosophila melanogaster with 2 samples.

How the data were processed

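Chromatin immunoprecipitation with sequencing (ChIP-seq) was measured in 2 biological replicates of Drosophila melanogaster embryos of mixed sex, collected between 0 and 24 h. The line carries CG7987 fused to GFP at its C-terminal end, and per the labels chromatin was sheared by sonication to a size range of 200 to 800. The labels conflict on what the libraries are: the assay and antibody labels call them ChIP for CG7987, while a free-text line calls them the input control of that ChIP. They were treated here as ChIP, which no value below tests.

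Per the labels the coordinates are on dm6. Per the deposited readme texts, candidate peaks were called for each replicate and for the pooled replicates, each against a single control library. The deposited list of peaks kept by an irreproducible discovery rate (IDR) threshold was derived from those lists. The aligner, the peak caller and the threshold are not given in the sources used here. Each candidate list holds exactly 30000 peaks, so its length carries no information on the amount of binding. The pooled candidate list is labelled as peaks and background, so its weaker entries may be background. The IDR list holds 4410 peaks, and these are the 4410 strongest peaks of the pooled list.

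Each deposited peak carries a signal value, the strength given by the authors' caller, on a scale that is not given in the sources used here. The deposited −log10 q-value is tied at its maximum in all 4410 IDR peaks, so peaks were ranked by signal. Signal is the authors' own value and was used mainly to describe, rank or select peaks within a list. It was also correlated between replicates, rescaled on X, and compared between promoter summits of ribosomal protein genes and others. Read counts were not used here, so the depth of each library is unknown. Alignments and signal tracks were not used here. Exact Clopper-Pearson intervals at 95% cover counting error over peaks or genes only.

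Summits were set against the Ensembl 115 annotation of assembly BDGP 6.54, without annotated transposable elements, and against the RefSeq genome sequence. All peaks used lay inside the 6 chromosome arms of that sequence, except 1 replicate 1 candidate on Y, which was left out. Coordinates are counted from 1. The arms hold 18164 genes, of which 13945 are protein-coding, and 23581 distinct transcription start sites (TSSs). Each summit was put into the first matching class of 7: within 500 bp of a TSS (the promoter window), 5′ UTR, coding exon, 3′ UTR, other exon, intron and intergenic. A gene with a summit within 500 bp of any of its TSSs is called bound. The same summit can count for several genes, and it may lie inside a neighbouring gene. Shares and distances were compared with 100 random rotations of the summits along their arms, in two-sided permutation tests whose smallest p is 0.0198. Shares of bound genes were compared with two-sided Fisher's exact tests. Gene lists were set against all other protein-coding genes, and the transfer, small nuclear and small nucleolar RNA lists against all other genes of the annotation. Gene lists, 24 in all, and 19 sequence motifs were fixed before the data were examined. Matches within 50 bp of a summit were compared with windows of the same 101 bp length centred 400 bp to the left and right, with an exact binomial test on the peaks that differed, keeping the larger p of both sides. All 2080 6-mers, merged with their reverse complements, were tested in the same way. Values were adjusted by the Benjamini-Hochberg method within each family, at a threshold of 0.05. Because neighbouring genes and summits are not independent, these p-values describe this peak list and not further embryo collections.

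With 1 group there was no comparison between groups, and the replicates were compared with each other. Genes are named by a rule fixed in advance: the nearest gene of the 15 strongest IDR peaks, up to 3 bound members of each list by signal, CG7987 itself, and up to 2 unbound members of a list reported as less often bound. The other bound insulator genes, His3.3B, RpL13 and genes given only to place a peak fall outside this rule and were named after their values were seen. Of the list symbols, 5 were matched through another symbol and 1 was not found. From the list of histone genes, 3 genes that match it by name only were left out. Alternatives covered the promoter window, the stronger part of the list, each replicate alone, the random model, the TSS set, the match between peaks, the control windows, all pooled candidates and an X dose correction. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The functions were tested on simulated data. Random summits gave 0 called classes and 0 called lists of 24, and 20 of 20 planted words were recovered among 2080, with 0 called when none was planted. The random summits were 1 draw placed evenly along the arms, and the simulated windows were not paired by peak. These runs therefore check the functions and do not give the error rate in these data.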

Results

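Both ChIP-seq libraries come from Drosophila embryos of a line that expresses CG7987 fused to GFP, and they form 1 group of 2 biological replicates. The main list of 4410 IDR peaks had a median width of 376 bp, and its signal ran from 139 to 11622 with a median of 201. Each candidate list, for replicate 1, replicate 2 and their pool, held 30000 peaks. Sequencing depth is unknown from the lists used here. A line of the labels calls both libraries an input control, so the values below describe where signal was found, with that conflict open.

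The strongest regions were shared by the replicates. The peak at Drat ranked 1 in replicate 1 and 2 in replicate 2, and the peak summit in an intron of ush next to cbt ranked 2 and 1. The first 5 IDR peaks, at Drat, cbt and larp, all ranked within the first 5 of each replicate. Not every named promoter was as even. The peak 258 bp upstream of elav, a gene used as a marker of neurons, lies inside the gene arg. It ranked 273 in replicate 2 and 20817 in replicate 1. The peak at the proteasome gene Rpn9 ranked 3031 in replicate 1 and 17356 in replicate 2. Each rank is that of the overlapping replicate peak with the nearest summit, so a weaker neighbouring peak may stand in for some. Of all replicate 1 candidates, 61.1% (95% CI 60.5 to 61.6) were overlapped by at least 1 bp by a replicate 2 candidate, against 12.9% after rotation (permutation p = 0.0198, the smallest the rotations can give). With a reciprocal overlap of 50% the share was 43.9%, and with summits within 100 bp it was 40.7%. For replicate 2 candidates in replicate 1 the shares by these 3 criteria were 66.0%, 44.6% and 40.7%. Among the 4410 strongest peaks of each replicate the share was 62.2% (60.8 to 63.7) against 1.84% after rotation (permutation p = 0.0198). Of the IDR peaks, 86.6% were overlapped by a peak among the 4410 strongest of replicate 2, and 73.2% by a peak among those of replicate 1. Across 4342 IDR peaks matched in both replicates, log10 signal gave a Pearson r of 0.497 and a Spearman rho of 0.353. Across all 18322 matched candidates these were 0.674 and 0.576. The IDR peaks are the strongest of the pooled list, a narrower range of signal, so the correlations of both sets are not directly comparable. Peaks are not independent replicates, so no p is given for these correlations.

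Signal was highest at a handful of loci. The first was Drat (FBgn0033188, 2R 7526118 to 7532981, minus strand), where a peak of 2295 bp from 7529122 to 7531416 had its summit at 7530956, 61 bp upstream of a TSS, with a signal of 11622. The second was a peak of 3753 bp on 2L from 478643 to 482395, next to cbt (FBgn0043364, 2L 476446 to 479688, minus strand), a zinc finger transcription factor, and inside the gene of ush, a GATA cofactor. It held summits at 481293 in an intron of ush (signal 11450), at 479186 in the 5′ UTR of cbt (9055) and at 480310 in an intron of ush (5551). A further ush intron peak, with a summit at 484598, reached 2434. Outside both loci the highest signal was 3224, at the promoter of larp (3R, summit 28326429), which encodes an RNA-binding protein. Next came an intron of sima (3R, 30103063, 2737), the fly hypoxia-inducible factor subunit, an intron of sbb (2R, 18337191, 2109), and a site 756 bp upstream of jp (2L, 9567506, 2018). The promoters of lncRNA:CR31840 (1972), CG14100 (1969), the UDP-galactose transporter gene Ugalt (1844) and the mannosyltransferase gene Alg3 (1774) followed. Signals of 1804 in the 5′ UTR of CG11050 and 1714 at an intergenic site near CG3348 completed the 15 strongest peaks.

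**Figure D1:**
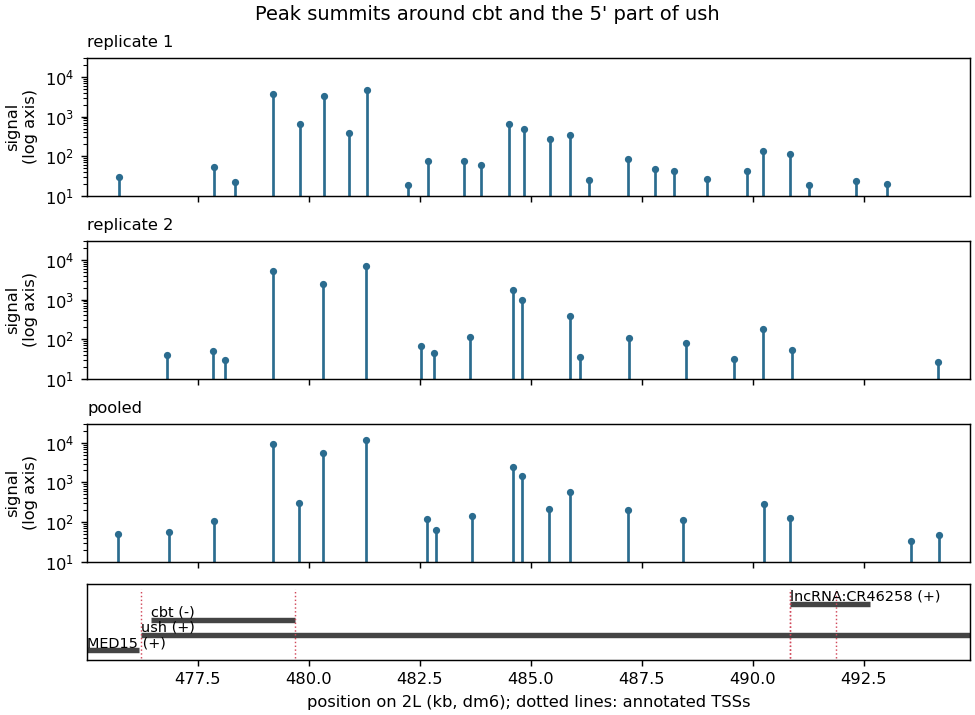
Signal of each peak summit (log axis) in the candidate lists of replicate 1, replicate 2 and the pool, by position on 2L in kb, with the annotated genes below and TSSs as dotted lines. The 3 highest pooled summits, with signals of 11450, 9055 and 5551, lie around the start of cbt in both replicates, and scales differ between lists.

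At the gene of the tagged protein no IDR peak was found. CG7987 (FBgn0038244) lies on 3R from 14570472 to 14575887, and the only IDR peak within 20 kb of it had its summit at 14558569, 11903 bp away and nearest to Pde6, with a signal of 280 and rank 1085. Below the IDR threshold, the pooled list held 2 candidates with summits inside CG7987, at 14575875 near its TSS (signal 106, rank 6757) and at 14574965 (55.0, rank 16484).

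Summits lay mainly at promoters. Of 4410 summits, 2560 (58.0%, 95% CI 56.6 to 59.5) were within 500 bp of a TSS, against 13.5% ± 0.834 (SD of 100 rotations), a ratio of 4.30. Coding exons outside promoter windows held 19 summits (0.431%, 0.260 to 0.672) against 13.4% after rotation, and 0.771% without replicate 2. Introns held 30.2% against 39.2%, intergenic sequence 8.87% against 28.0%, and 3′ UTRs 1.02% against 4.27%. All 5 of these differences had a permutation p of 0.0198, the smallest possible, and an adjusted p of 0.0277. Shares of 0.771% in 5′ UTRs (0.771% after rotation, adjusted permutation p = 1) and 0.658% in other exons (0.826%, adjusted permutation p = 0.370) did not pass the threshold. Over all 30000 pooled candidates, promoter windows held 35.3%, coding exons 6.35% and introns 39.9%, the last no longer below its rotations (39.2%, adjusted permutation p = 0.535). The median distance to the nearest TSS was 253 bp, against 3411 bp after rotation (permutation p = 0.0198), and 1104 bp over all pooled candidates. Within promoter windows, 1702 of 2560 summits (66.5%, 64.6 to 68.3) lay upstream of the nearest TSS, with a median position of -35 bp. Peak strength within the IDR list showed no detectable relation to this: promoter windows held 57.3% of the strongest 1102 peaks and 56.5% of the weakest 1104 (odds ratio 1.03, Fisher's exact p = 0.731). Over all 30000 pooled candidates the shares were 55.8% of the strongest 7500 and 20.9% of the weakest 7500, an odds ratio of 4.77, a comparison chosen after the data were examined. The weaker of these candidates may be background, which was not separated from weak binding.

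**Figure D2:**
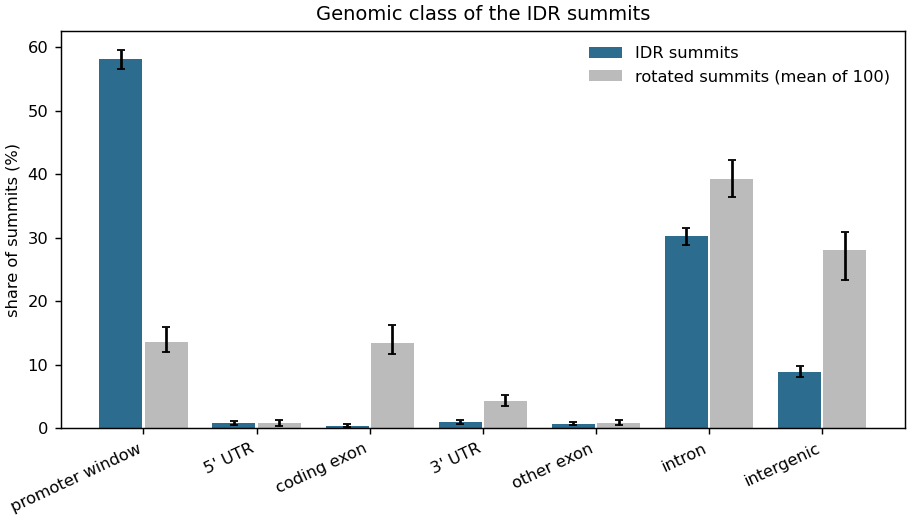
Share of summits (%) in each genomic class for the 4410 IDR summits, with exact 95% intervals, and for the mean of 100 rotations, with bars from the lowest to the highest rotation. Promoter windows hold 58.0% against 13.5% and coding exons 0.431% against 13.4%.

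**Figure D3:**
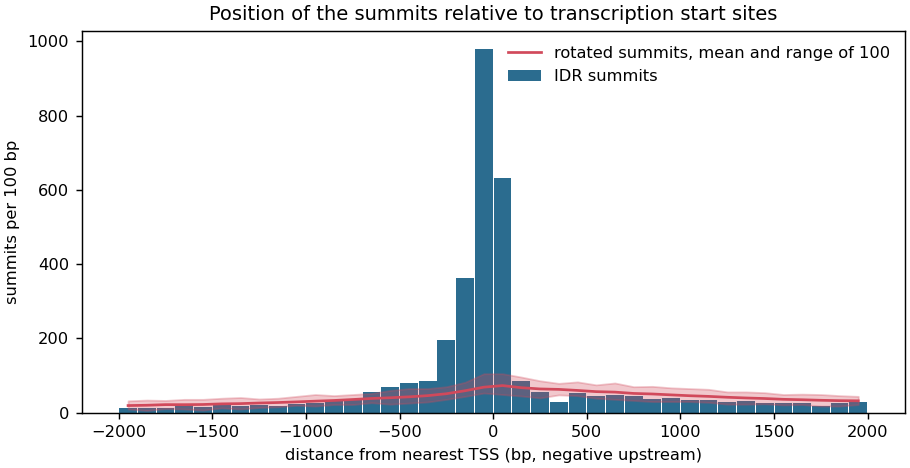
Number of IDR summits per 100 bp by distance to the nearest TSS in bp, negative upstream, with the mean (line) and range (band) of 100 rotations. The highest bin, of 978 summits, covers the 100 bp upstream of a TSS.

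In the IDR list bound promoters were fewer on X and on chromosome 4. In all, 2857 of 13945 protein-coding genes (20.5%) were bound. On the arms 2L, 2R, 3L and 3R the shares lay between 20.1% and 22.1%, 2501 of 11669 genes together (21.4%). On X 351 of 2196 genes were bound (16.0%), an odds ratio of 0.698 (Fisher's exact test, adjusted p = 6.92e-09). On chromosome 4, a small and largely heterochromatic chromosome, 5 of 80 genes were bound (6.25%, odds ratio 0.267, adjusted exact p = 3.16e-04). The direction for X turned over all 30000 pooled candidates (odds ratio 1.13, adjusted exact p = 0.00874) and with X signals divided by 0.75, the X dose of an even mix of sexes (1.24, adjusted exact p = 2.74e-04). For chromosome 4 the odds ratio was 0.485 without replicate 1 (adjusted exact p = 0.0277), 0.228 without replicate 2 and 0.178 over all candidates. The segment polarity gene ci was among those 5, with a signal of 325 at 104 bp from its TSS.

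Genes of cytoplasmic ribosomal proteins stood out among the 24 lists. Of 93 members 74 were bound (79.6%, 95% CI 69.9 to 87.2), against 20.1% of other protein-coding genes (odds ratio 15.2, Fisher's exact test, adjusted p = 5.48e-33). Their highest signals were at RpS27 (3R, summit 25247509, signal 1687, 5 bp from the TSS), RpL7 (2L, 10201026, 1594, 22 bp) and RpL14 (3L, 8600990, 1225, 16 bp). Genes of insulator and architectural proteins, which organise chromatin domains, were bound in 8 of 14 cases (57.1%, 28.9 to 82.3, adjusted exact p = 0.0112): CTCF, su(Hw), BEAF-32, Cp190 (signal 379), Trl, Dref (925), pzg and Chro (1114). The summit at Dref lies 84 bp upstream of its TSS and inside RpL13, a gene of the ribosomal protein list that was also bound. Replication and cell cycle genes were bound in 12 of 30 cases (40.0%, 22.7 to 59.4, adjusted exact p = 0.0427), with dup (353), Dp (288) and Orc1 (241) highest. The Orc1 peak belongs to the Drat locus, taken as IDR peaks at most 5 kb apart, for which a copy number gain stays open. Against rotated summits, where the smallest permutation p of 0.0198 becomes 0.475 when adjusted over the 24 lists and so could hardly give a call, the unadjusted p was 0.0198 for ribosomal protein, 0.238 for insulator and 0.277 for replication genes. Rotation left 13.5% of summits at promoters instead of 58.0%, so ratios of small lists swung widely. They ran from 0 to 7.38 for insulator and from 0 to 3.75 for replication genes, so the rotations say little on either call. By Fisher's exact test the insulator call (odds ratio 5.09) was lost without replicate 2 (3.12, adjusted exact p = 0.163) and in the stronger part of the list (4.75, 0.0629), and the replication call (2.63) without replicate 1 (2.62, 0.0615), without replicate 2 (1.54, 0.531), in the stronger part (1.39, 0.899), with the 1000 bp window (2.51, 0.0558) and with genes grouped by their number of TSSs (Mantel-Haenszel test, 2.41).

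Other lists for basic cell functions did not pass the threshold. Mitochondrial ribosomal proteins were bound in 23 of 73 cases (31.5%, adjusted exact p = 0.0837, and 0.0110 without replicate 1), with signals of 1273 at mRpS23, 1148 at mRpL41 and 1067 at mRpS10. Oxidative phosphorylation genes were bound in 23 of 80 (28.8%, adjusted exact p = 0.171), among them ND-ASHI (419), ATPsynF (236) and COX5A (228). The proteasome list had 7 of 48 (14.6%, adjusted exact p = 0.560), led by Rpt5 (214), Rpn6 (207) and Rpn9 (186). TBP and its associated factors had 2 of 16, Taf4 (369) and Taf5 (181), with an adjusted exact p of 0.777. Polycomb and trithorax genes had 8 of 23 (34.8%, adjusted exact p = 0.252), with ph-p (1297), brm (630) and E(z) (380) highest. Heat shock genes had 4 of 16 (adjusted exact p = 0.898), with Hsp83 (1571), Hsp27 (613) and Hsp26 (189) highest.

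Developmental and tissue lists did not pass it either. Gap, pair-rule and segment polarity genes were bound in 5 of 21 cases (adjusted exact p = 0.898), including ci, hry (signal 230) and wg (162). Dorsoventral and mesoderm genes had 6 of 18 (adjusted exact p = 0.404), with tin (340), brk (243) and Mef2 (205) highest. The Enhancer of split complex had 2 of 11 (adjusted exact p = 1), E(spl)m3-HLH (275) and E(spl)m7-HLH (171), and the neural list 1 of 17, elav (435), with an adjusted exact p of 0.404. The elav summit lies inside arg, so it cannot be assigned to elav alone. Muscle structural genes had 2 of 14, sls (228) and Tm1 (177), with an adjusted exact p of 0.898. Germline and piRNA genes had 3 of 18, bgcn (898), cuff (326) and nanos (246), with an adjusted exact p of 1. None of the 18 neuronal channel and synapse genes was bound (adjusted exact p = 0.0928, and 0.0453 with the 1000 bp window), none of the 8 Hox genes (0.560), none of the 6 dosage compensation genes (0.812) and none of the 9 yolk and chorion genes (0.404). Exact upper bounds of these 4 shares were 18.5%, 36.9%, 45.9% and 33.6%.

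Lists bound less often than other genes were chemoreceptors, histones, transfer RNA and small nucleolar RNA genes. Of 179 chemoreceptor genes, which few embryonic cells express, 1 was bound (0.559%, adjusted exact p = 9.89e-16). That was Gr63a, with a signal of 186, while Or85c and Gr93c had no such summit. Histone genes were bound in 4 of 115 cases (adjusted exact p = 1.37e-06), and that count splits by gene type. None of the 111 replication-dependent copies on 2L, such as His2A:CG33832 and His1:CG33816, was bound. All 4 other histone genes were, with signals of 188 at His2Av, 169 at His4r and 165 at His3.3A, besides His3.3B. The 2L copies are near-identical repeats, to which short reads may not be assigned uniquely. Whether this accounts for their count was not tested. Transfer RNA genes were bound in 27 of 290 cases (9.31%, against 17.4% of all other genes, adjusted exact p = 7.44e-04), with 661 at tRNA:Trp-CCA-2-2, 629 at tRNA:Tyr-GTA-1-8 and 519 at tRNA:Ala-TGC-2-1, and no summit at tRNA:Leu-TAG-1-1 or tRNA:Pro-TGG-1-5. Small nucleolar RNA genes had 23 of 269 (8.55%, against 17.4% of all other genes, adjusted exact p = 3.57e-04). Their highest summits, 1307 at snoRNA:Psi28S-2949 and snoRNA:Or-aca5 and 1225 at snoRNA:U49:66Da, are 2 peaks, the latter that of RpL14, and snoRNA:Psi28S-3405d and snoRNA:Me28S-A2564 had none. The small nuclear RNA list had 5 of 32 (adjusted exact p = 1), with 301 at snRNA:U1:95Ca and 244 at 1 peak between snRNA:U6:96Ab and snRNA:U6:96Ac. Against rotated summits the histone ratio of 0.170 lay within the range of the rotations, 0 to 3.68 (unadjusted permutation p = 0.436), and unadjusted permutation p was 0.416 for tRNA, 0.356 for snoRNA and 0.0396 for chemoreceptor genes. By the exact test the tRNA call (odds ratio 0.496) was lost without replicate 2 (0.682, adjusted exact p = 0.128) and the snoRNA call (0.453) in the stronger part of the list (odds ratio 0.680, adjusted exact p = 0.378), snoRNA genes turned to an odds ratio of 1.30 with the 1000 bp window (adjusted exact p = 0.166), and grouping genes by their number of TSSs (Mantel-Haenszel test) ended both calls (0.705 and 0.638).

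**Figure D4:**
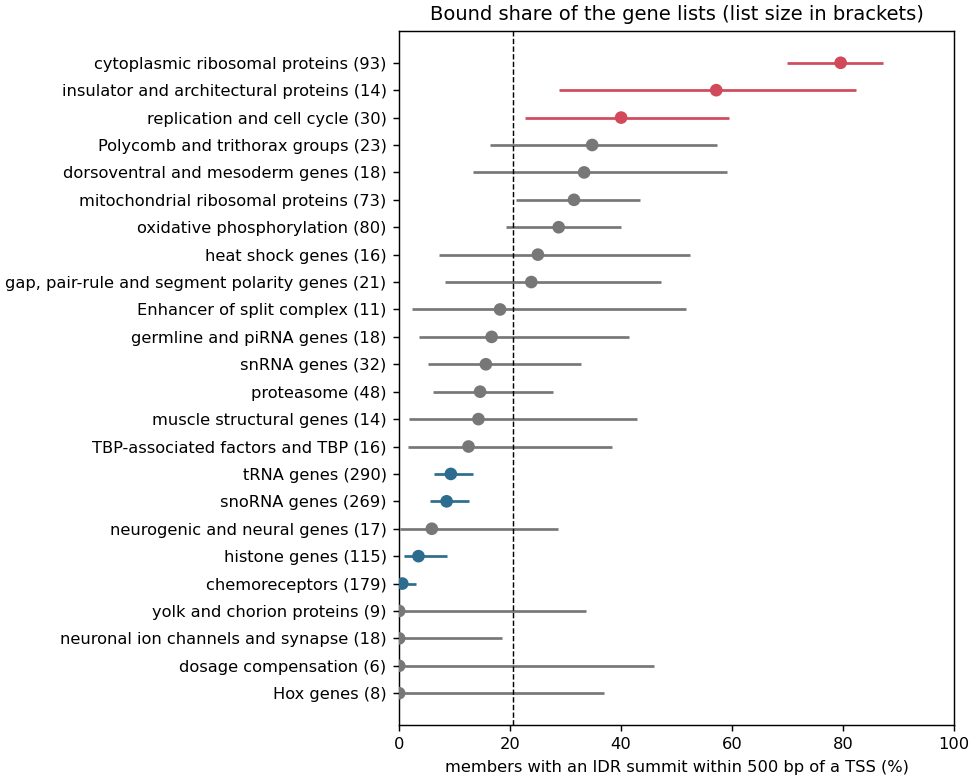
Share of each list's members (%) with an IDR summit within 500 bp of a TSS, with exact 95% intervals and list sizes in brackets. Red lists were bound more often and blue lists less often than other genes at an adjusted p below 0.05, and the dashed line marks the 20.5% of all protein-coding genes. The tRNA, snRNA and snoRNA lists were tested against all other genes, of which 17.2% to 17.4% were bound, and not against this line.

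Of 19 motifs, 7 were more frequent within 50 bp of the summits than beside them. The DNA replication-related element TATCGATA, bound by DREF, was in 123 of 4410 peaks (2.79%) against 0.363% of flanking windows (7.69-fold, exact binomial test, adjusted p = 5.92e-19). Core promoter motif 1, GGTCACACT, was in 93 (2.11%) against 0.181% (11.6-fold, adjusted exact p = 6.32e-18). The BEAF-32 core CGATA was in 20.2% against 11.4% (adjusted exact p = 7.07e-28), the CTCF core in 3.24% against 1.07% (adjusted exact p = 4.76e-12), and core promoter motif 7 in 3.51% against 1.34% (adjusted exact p = 5.48e-08). CGATA is contained in TATCGATA, so the 123 peaks with TATCGATA also count for the BEAF-32 core, and these motifs are not independent. Both E-boxes CACGTG (3.22% against 1.20%, adjusted exact p = 5.36e-10) and CAGCTG (7.19% against 4.24%, adjusted exact p = 1.41e-08) were also more frequent. The homeodomain word TAATTA was less frequent, 4.76% against 6.60% (adjusted exact p = 0.00151). The other 11 did not pass the threshold, among them the early embryonic activator site of Zelda (0.476% against 0.658%, adjusted exact p = 0.396), the GAGA repeat (3.11% against 2.44%, adjusted exact p = 0.302), the TATA box (2.70% against 2.63%, adjusted exact p = 0.796) and the heat shock element (2.40% against 2.51%, adjusted exact p = 0.535). TAATTA lost its call without replicate 1 (ratio 0.951, adjusted exact p = 0.951) and in the stronger part of the list (0.804, adjusted exact p = 0.468), and had a ratio of 0.410 without replicate 2. Without replicate 2 the GAGA repeat (1.90-fold, adjusted exact p = 1.20e-07), the initiator (1.02e-06), the CA repeat (0.00264) and the Su(Hw) core (0.0381) passed the threshold and TATCGATA was 4.27-fold, while motif 1 was 5.00-fold in the stronger part, and against unbound promoters these last were 1.78-fold and 1.90-fold. Of 2080 6-mers, 194 were more and 163 less frequent, against 123 and 170 without replicate 1 and 474 and 381 without replicate 2. Highest in rank were CGATAG (8.41% against 2.23%, adjusted exact p = 4.87e-34) and ACACTG (11.0% against 3.92%, adjusted exact p = 4.77e-33), and CCAGGA was the first of those less frequent (0.567% against 3.63%, adjusted exact p = 1.75e-21). At 400 bp to either side, 15.5% and 16.0% of positions were in coding sequence, against 1.18% at the summits. Whether coding sequence in the flanking windows gives the less frequent words was not tested.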

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

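The strongest pooled peaks are the IDR list itself, so that alternative moved nothing and says nothing on stability. Rotation within the candidate span, 1 summit per interval and all pooled candidates were chosen after seeing the data, and the dose correction for X after the share on X but before its own value was seen. Shares of the promoter window, coding exon, 3′ UTR, intron and intergenic classes, the median TSS distance, and the odds ratios for X and 4 kept direction and side of the threshold with other windows, in the stronger part, with each replicate alone and, where run, with other random models and TSS sets. Promoter shares ran from 49.9% (250 bp window) to 67.9% (1000 bp) in these runs, and the share was 35.3% over all pooled candidates. The odds ratio for X ran from 0.675 to 0.731 over the windows, the stronger part and each replicate alone. It turned to 1.13 over all pooled candidates and to 1.24 with the dose correction. The strength comparison passed no threshold in these runs, with odds ratios from 0.851 in the stronger part to 1.15 without replicate 1, but reached 4.77 over all pooled candidates. There the 5′ UTR share (1.27%) and the intron share (39.9%) also turned above their rotations. The 5′ UTR share passed the threshold with the 1000 bp window (0.181%). With summits within 100 bp, Spearman's rho was 0.412 over IDR peaks and 0.646 over all candidates. The stronger part of the list gave 1 list bound more often, 0 motifs less frequent, and 63 more and 46 less frequent 6-mers. Of these 6-mers 61 and 45 were called in the full list. With each replicate alone, lists bound more often numbered 1 to 3, motifs more frequent 7 to 11 and less frequent 0 to 1, 6-mers more frequent 123 to 474 and less frequent 170 to 381. Rotated summits called 0 lists more and 0 less often, which says nothing on stability, since the smallest p of 100 rotations becomes 0.475 over 24 lists. Unadjusted permutation p was 0.0198 for ribosomal protein genes (ratio 3.88, highest rotation 2.42) and 0.0396 for chemoreceptors (0.0273). Insulator (2.79), replication (1.95), histone (0.170), tRNA (0.540) and snoRNA genes (0.496) lay within their rotations, with unadjusted permutation p from 0.238 to 0.436. Rotated ratios of small lists ranged widely, such as 0 to 7.38 for insulator genes, so lying within them is weak evidence against a call. Windows of 100 bp either side gave 11 motifs more frequent. With unbound promoters as control, 12 motifs were more and 3 less frequent, and 273 6-mers less frequent. The TATA box (ratio 0.640) and the initiator (0.863) then fell below their control, and snoRNA genes turned to an odds ratio of 1.30 with the 1000 bp window. The cause was not tested. Leaving out rotated summits and the strongest pooled peaks, 262 runs of the single motifs, lists and overlaps were counted as unchanged. In those, motifs and lists kept their call or lack of one, and overlap shares stayed above all rotations. A call was lost in 13 runs and gained in 17. In the 3 named above, direction turned with a call in the main run, the alternative or both. For motifs and lists without a call in either run, direction was not compared, so some of the 262 may have turned. Depth is unknown, so its effect on weak peaks could not be measured. No paired analysis was possible because the series has 1 group.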

Other observations

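The tests in this part on base composition, on the replicates and repeats of the strongest loci, and both adjustments for X were chosen after the patterns but before their own values were seen, and the others after the results were seen. Promoter and other summits carried different words. Promoter sequence alone could give such contrasts, since no unbound sites were split in the same way. TATCGATA was in 123 of 2560 promoter summits and in 0 of 1850 others (Fisher's exact test, adjusted p = 5.55e-29), and core promoter motif 1 in 92 and 1 (adjusted exact p = 2.84e-20). The BEAF-32 core, which TATCGATA contains, was in 25.1% and 13.4% (adjusted exact p = 2.64e-21). The CTCF core went the other way, with 2.66% and 4.05% (adjusted exact p = 0.0258), and exceeded its flanks in both sets. The twist-type E-box (2.97% and 5.68%, adjusted exact p = 3.22e-05), the Su(Hw) core (0.391% and 1.14%, adjusted exact p = 0.0125) and the CA repeat (3.16% and 4.59%, adjusted exact p = 0.0304) were also more frequent outside promoters, without passing the threshold against their flanks in either set. CACGTG, at 2.85% and 3.73%, did not differ detectably between them (adjusted exact p = 0.206) and also exceeded its flanks in both. Among non-promoter summits, CACGTG and the CTCF core were the motifs of the 19 that passed the threshold.

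Longer words that are not exact matches of the fixed motifs were also more frequent at summits than in their flanking windows. They were not compared with unbound promoters. For words found mainly at promoter summits, promoter sequence alone could therefore give the contrast. Among 8-mers, with a Bonferroni adjustment over all 32896, CAACACTG was in 126 peaks against 15 and 11 of the left and right flanking windows (adjusted exact p = 6.21e-19), and 118 of the 126 were promoter summits. CAGCCCTG was in 69 peaks against 2 and 5 (adjusted exact p = 6.03e-11), and 61 of the 69 were promoter summits. This word differs from the pattern used for core promoter motif 7, CAKCNCTA, only in its last base, so it may be a form of that motif. GCAAACAA was in 129 peaks against 51 and 47 (adjusted exact p = 1.48e-04), in 1.80% of promoter and 4.49% of other summits. Promoter summits of ribosomal protein genes were also stronger than others: the 80 summits had a median signal of 464, against 199 for the other 2480 promoter summits (permutation p = 1e-05, the smallest that 100000 resamples can give).

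The near absence of summits from coding exons (0.431%) is a pattern that base composition and promoter distance were tested for. Random positions matched to the summits on arm and GC content of 101 bp fell in coding exons in 13.7% of cases, and positions at the same distances from random TSSs in 10.3%, so neither accounts for it as the whole cause. The share of positions in any coding sequence was 1.18% at the summits and 23.6% and 24.9% at 1000 bp to either side. In the pooled list, coding exons held 0.450% of the strongest 6000 candidates and 14.4% of the weakest 6000, near the 13.4% of rotated IDR summits. The weakest candidates may be background, so this does not show that weaker binding reaches coding exons. Whether the control library or a chromatin property is behind the near absence stays open, and no biological explanation was tested, as the design has 1 group.

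The cbt and Drat loci, taken as IDR peaks at most 5 kb apart, held 11 and 7 of the 4410 peaks and 2.67% and 1.25% of all summed signal. An origin in only 1 of the 2 replicates is excluded by the ranks: the lowest rank of either locus in either replicate was 2. These ranks do not cover the single control library that both replicates share. Known repeated sequence is argued against by soft-masking, which covers 12.3% of the cbt locus and 16.3% of the Drat locus. A copy number gain in this line, or a duplication missing from the reference, stays open, since both replicates share the line and the control. No biological explanation was tested.

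The lower share of bound promoters on X could reflect X copy number in mixed-sex embryos. Dividing X signals by 0.75, the X dose of an even mix of sexes, and keeping the 4410 strongest pooled peaks turned the odds ratio to 1.24 (95% CI 1.11 to 1.38), past 1 instead of to it. So a dose effect of this kind is more than large enough, but its size was not matched. That an interval wholly above 1 leaves the question open was settled after this value was seen. It would also be weaker if the signal is already relative to a control with the same X dose, so this explanation and others cannot be told apart. Gene content by number of TSSs is argued against, since stratifying gave 0.614 (0.541 to 0.698). Over all 30000 pooled candidates, of which the weaker may be background, X was not below the autosomes (1.13, 1.03 to 1.24). No biological explanation was tested.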
